A study of Mus musculus with 3 samples.

How the data were processed

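Expression was measured in primary mouse embryonic fibroblasts from embryos of embryonic day 12.5, untreated and grown in DMEM with 10% serum, with 1 µg of total RNA labelled per sample, per the labels' protocols. Each of 3 Agilent 2-colour arrays held 1 sample labelled wild type in Cy5 and 1 sample labelled SA1-null in Cy3. No array had the dyes the other way round, so dye and genotype cannot be told apart. The labels call the arrays biological replicates 1 to 3.

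The scanner files were made by Agilent Feature Extraction 10.1.1.1 for replicate 1 and 10.7.3.1 for replicates 2 and 3, per the file headers. They hold spot and local background intensity values per dye and, per the file headers, processed intensity values that had been background-subtracted, spatially detrended and dye-normalized. Their log ratio is the log10 of processed Cy5 over Cy3, per the file headers. The deposited table of the whole series holds 1 log2 value per probe and array. Per the submitters' processing notes it was made with limma, and its version, background correction and normalization are not given in the sources used here. Set against the log ratios computed here, the deposited log2 values ran as Cy5 over Cy3, with correlations of 0.985, 0.983 and 0.997 across probes and slopes of 0.957, 1.03 and 1.00. Their medians were -0.02, -0.02 and -0.01. Their scale and direction follow from this comparison, and how they were centred stays unknown.

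The design fixed before the data were examined named mean spot signals. The files hold median signals, which were used instead. Signals were corrected for background with normexp and an offset of 50 and normalized by loess within each array in limma 3.58.1 under R 4.3.3. Control spots and spots with outlier flags had weight 0 in the loess, and then were left out (116, 125 and 207 flagged spots on the 3 arrays). No spot was saturated in the sense of the files' flags (0 on each array). Ratios were turned to log2 of the channel labelled SA1-null over the channel labelled wild type. The 41174 probes were reduced to the 24015 that were well above background in at least 1 of the channels on all 3 arrays. The probe with the highest mean intensity stood for each gene, which left 18485 genes or transcripts.

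The files name transcripts and not genes. Of the probes, 23374 matched a transcript of 16535 genes in the RefSeq gene table of assembly GRCm38.p6 without versions. The array design names another assembly, so no coordinates are printed, and the table served only for names and for which genes neighbour Stag1. Of the genes tested, 12032 had a symbol and 6453 kept the accession in the file. Of 4486 genes with several kept probes, 1469 had probes of opposite sign and 45 had probes over 1 log2 unit apart.

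The mean log2 ratio of each gene was tested against 0 with lmFit and eBayes in limma, and p-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. SD values are over the 3 arrays. A test that only turns the signs of 3 arrays cannot give a two-sided p under 0.25, so each call rests on the spread that limma shares between genes. The 29 gene lists were written before the data were examined, and 28 had at least 3 measured members. They were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation as an alternative. Member counts are given over all genes and adjusted over the list alone. The genes named are Stag1, Stag2 and Myc, the 10 with the largest rise and the 10 with the largest fall, and list members. Only genes with the same sign on all 3 arrays could enter the 10 of either direction. List members were drawn from the up to 4 with the smallest p in each list, or 6 in lists that were called. Not all of those are named. In a direction with fewer than 10 called genes with a symbol, those with the smallest p fill the 10 and are said not to pass.

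Precision is limited by the 3 arrays. In ratios simulated with the spread of the 18485 genes and 200 changed genes, the test recovered 0% of the genes changed 2-fold, 37.3% of those changed 4-fold and 68.2% of those changed 8-fold, with 2 false calls. In simulated data with 1 list shifted by 0.6, camera called that list and 0 of the 27 others. Camera with its preset correlation was tested there on genes that vary independently, which the real genes do not.

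The alternatives were no background subtraction, an offset of 0, the processed signals of Feature Extraction, median centring, scale normalization between arrays, the deposited values, other filters on dim probes, flagged spots kept, other rules for several probes, other variance models, both channels as separate samples, the slide as a term, each replicate left out, a threshold of 0.1, other set tests, and other windows around Stag1. Array weights were added after seeing the data. Replicate 1 was on 1 slide and replicates 2 and 3 on another. The slide as a random block could not be estimated from 3 arrays. Figures were drawn with matplotlib 3.10.9.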

Results

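Primary mouse embryonic fibroblasts, connective tissue cells grown out of embryos, were compared between cultures labelled SA1-null and cultures labelled wild type. SA1 is a subunit of cohesin, the ring-shaped complex that holds sister chromatids together and shapes chromatin loops, and its relative SA2 takes the same place in other cohesin complexes. The series asks what SA1 does in gene regulation and development. RNA of 1 culture of each kind shared each of 3 arrays, with the sample labelled wild type in Cy5 and the sample labelled SA1-null in Cy3. In Cy3, 60.7%, 60.6% and 65.9% of probes were well above background on replicates 1, 2 and 3, against 67.0%, 63.0% and 61.9% in Cy5. The median spot signal of each array was 2.98, 1.84 and 2.59 times its median background in Cy3 and 4.02, 2.11 and 1.96 times in Cy5.

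Stag1, the gene that encodes SA1, was 11.4-fold higher in the channel labelled SA1-null (log2 ratio 3.52 ± 0.21, SD, n = 3, limma adjusted p = 0.0273), on 3 of 3 arrays. This goes against the labels. All ratios here are the channel labelled SA1-null over the channel labelled wild type, and every sign turns over if the channel labels are exchanged. The deposited values of the series run the other way, as Cy5 over Cy3, and their means over all Stag1 probes, dim ones included, were -2.47, -2.52 and -2.37. The next brightest Stag1 probe gave 3.53 ± 0.35 and the next, above background in Cy5 on 2 of 3 arrays, 2.17 ± 0.53 (SD, n = 3). The dimmest was not well above background in Cy5 on any array (0 of 3), and no fold is given for it, although its sign was the same. Before any correction the brightest probe read 1334, 1263 and 2029.5 in Cy3 and 388, 161 and 167.5 in Cy5. The labels do not say which part of Stag1 was disrupted. A probe outside that part could stay unchanged, but the 2 brightest probes were not unchanged (3.52 and 3.53). Stag2, which encodes SA2, did not pass the test (-0.11 ± 0.12, SD, n = 3, limma adjusted p = 0.856), and its second probe had the opposite sign (0.38 ± 0.27). Myc, a transcription factor that drives growth, did not pass either (0.58 ± 0.43, limma adjusted p = 0.662), and its 3 probes lay between 0.40 and 0.62.

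**Figure D1:**
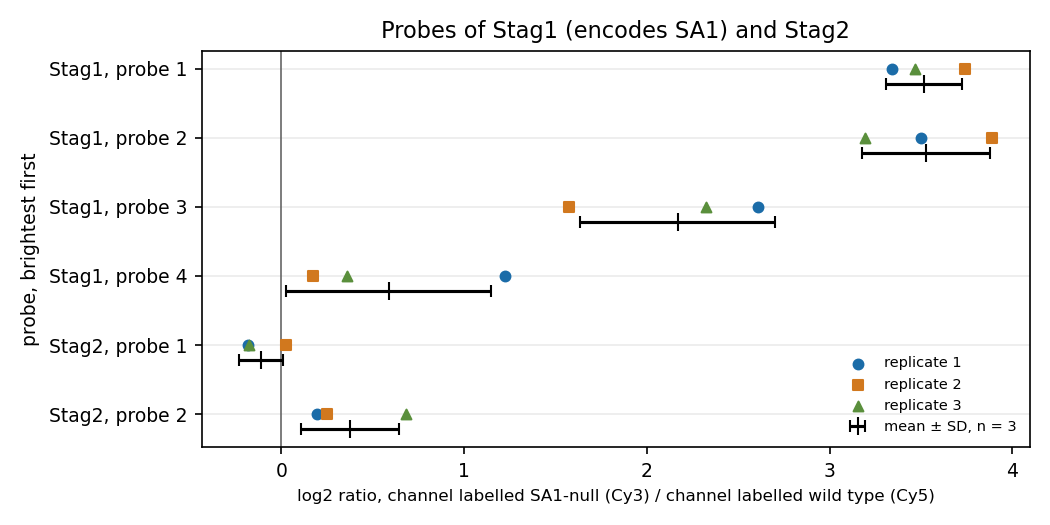
Each point is the log2 ratio of the channel labelled SA1-null over the channel labelled wild type (x axis) of a Stag1 or Stag2 probe (y axis) on 1 array, with the mean ± SD of 3 arrays under it. All 12 Stag1 values lie above 0, against the labels, those of the dimmest probe against a Cy5 signal at background, and all signs turn over if the channel labels are exchanged.

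Besides Stag1, the largest differences among called genes with a symbol were in genes known from macrophages and other blood cells. These were higher in the channel labelled wild type. Of 18485 genes and transcripts tested, 58 passed the threshold, and the fixed list of macrophage and blood cell markers held 9 of them. The channel labelled wild type was higher for 56 of them, 46 with a gene symbol, and the channel labelled SA1-null for 2. Among called genes with a symbol, Ctss, a lysosomal protease of antigen-presenting cells, fell by the most (-4.15 ± 0.73, SD, n = 3, limma adjusted p = 0.0312, 17.7-fold). It was followed by Srgn, a proteoglycan of blood cell granules (-3.76 ± 0.59, adjusted p = 0.0275 in limma), the lectin receptor Clec4n (-3.63 ± 0.24) and the lysozyme Lyz1 (-3.62 ± 0.23). Clec5a, Cd52, the NADPH oxidase subunit Ncf4, the myeloid signalling adaptor Tyrobp, Ms4a7 and the lipid receptor Trem2 lay between -3.39 and -3.07 at their brightest probes. The second Trem2 probe was at -2.19. The other Clec5a probes were weaker, 1 at -1.37 with Cy3 above background on 1 of 3 arrays, and 1 with Cy3 above background on none, for which no value is given. Each of these 10 was lower on 3 of 3 arrays, which the naming rule required. Pxylp1, a phosphatase of proteoglycan synthesis, was the other gene higher in the channel labelled SA1-null (2.03 ± 0.26, limma adjusted p = 0.0425). Its second probe was not well above background in Cy5 on any array, and no value is given for it, although its sign was the same.

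The genes next in that direction did not pass the test. Ly6a, a surface antigen of stem cells, had a log2 ratio of 1.64 ± 0.23 (SD, n = 3, limma adjusted p = 0.0566). The matrix genes Efemp1 (2.21 ± 0.79) and Ecm1 (1.14 ± 0.09), the stromal antigen Cd248 (1.19 ± 0.33), and Nrn1, Sned1, Eps8 and Sncg (0.91 to 1.59) were above 0 on 3 of 3 arrays, with adjusted p of 0.0927 to 0.178 in limma. For these genes too, the naming rule required the same sign on all arrays. The second Ecm1 probe was at 0.59. At an unadjusted p under 0.05, 1384 genes were found, 431 higher in the channel labelled SA1-null and 953 higher in the channel labelled wild type, where chance gives 924.25. In limma without replicate 2 and without replicate 3, 0 genes passed (1295 and 737 at an unadjusted p under 0.05). Without replicate 1, which leaves the arrays of 1 slide, 284 passed. Each of these counts rests on the spread between only 2 arrays. With the slide as a fixed term, slide 1 held 1 array, so the spread came only from the arrays of slide 2. The count of that fit, listed below with the other alternatives, is therefore not comparable with the count of the main analysis. Stag1 was at 3.47 in that fit, at 3.34 on the array of slide 1 and at a mean of 3.61 on the arrays of slide 2.

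**Figure D2:**
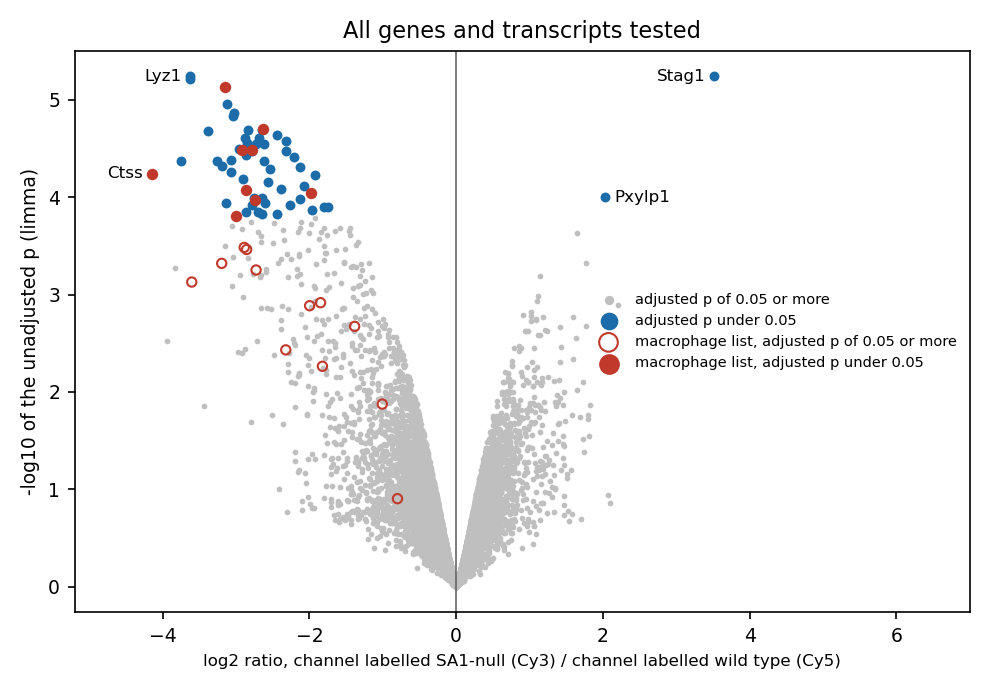
Each point is 1 of 18485 genes or transcripts, with its log2 ratio of the channel labelled SA1-null over the channel labelled wild type (x axis) and the -log10 of its unadjusted limma p (y axis). Of the 58 genes past the threshold (blue and filled red), 56 lie left of 0, and Stag1 and Pxylp1 lie right of 0. Stag1 goes against the labels, and all signs turn over if the channel labels are exchanged.

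**Figure D3:**
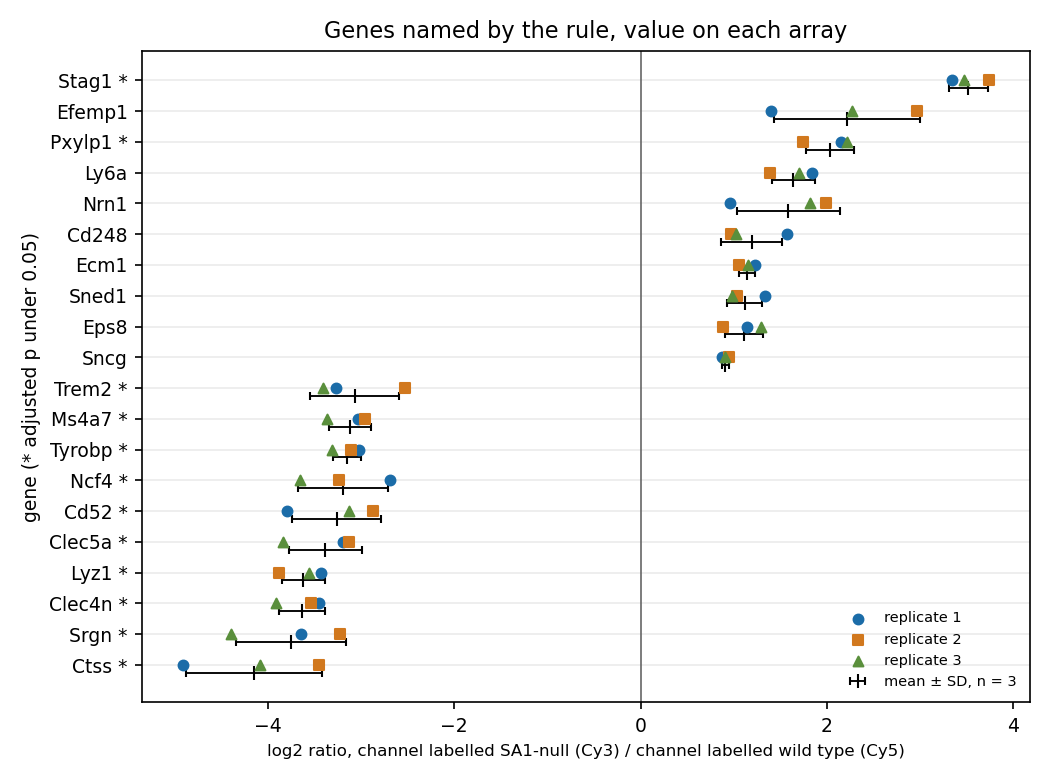
The log2 ratio of the channel labelled SA1-null over the channel labelled wild type (x axis) is drawn on each array for the 10 genes named in each direction (y axis), with mean ± SD (n = 3), and a star marks an adjusted p under 0.05. The 10 lower genes lie between -4.92 and -2.53 on every array, and the naming rule required the same sign on all arrays in both directions. Stag1 goes against the labels, and all signs turn over if the channel labels are exchanged.

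The list of macrophage and blood cell markers, fixed beforehand, was lower in the channel labelled SA1-null as a group. All 21 measured members were below 0 on 3 of 3 arrays, with a median log2 ratio of -2.74 (6.68-fold) and array medians of -3.02, -2.47 and -2.39. Adjusted over the list alone, 20 of these passed. Over all genes 9 passed, against 0.0659 expected among the 58 called genes (Fisher's exact test, two-sided p = 4.39e-18). That test takes genes as independent, which these members were not (estimated correlation 0.298). Tyrobp (-3.15 ± 0.15), the leukocyte surface antigen Ptprc (-2.92 ± 0.35, second probe -1.04, above background in Cy3 on 2 of 3 arrays), the complement subunit C1qc (-2.86 ± 0.49) and the scavenger receptor Msr1 (-2.63 ± 0.18) were among those that passed. Camera called the list (adjusted p = 8.15e-33), and the call was lost with an estimated correlation (adjusted p = 0.513 with an estimated correlation). Well above background in both channels on all arrays were 19 of the 21 members.

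Interferon-stimulated genes and inflammatory chemokines and cytokines were lower on the same side. Of 30 interferon-stimulated genes 23 were below 0, with a median of -0.25 (camera adjusted p = 1.14e-05, adjusted p = 0.513 with an estimated correlation). The median was -0.47 with an offset of 0, -0.53 with Agilent's processed signals, and -0.51 with median centring, which is -0.22 against all genes. It was nearer 0 with the slide as a fixed term (-0.13), with every probe on its own (-0.16) and with no filter on dim probes (-0.17). In the list 0 passed over all genes and 8 adjusted over the list alone, all 8 lower, among them the immunoproteasome subunits Psmb8 (-1.76 ± 0.30) and Psmb9 (-1.36 ± 0.23), the chemokine Cxcl10 (-1.52 ± 0.30) and Parp14 (-1.57 ± 0.40). Of 24 inflammatory genes 18 were below 0, with a median of -0.72 (camera adjusted p = 8.19e-05, adjusted p = 0.535 with an estimated correlation). The median was -1.11 with an offset of 0, -1.28 with Agilent's processed signals, and -1.22 with median centring, which is -0.92 against all genes. There 0 passed over all genes and 6 over the list alone, including the cytokines Tnf (-1.34 ± 0.29) and Il6 (-1.14 ± 0.48) and the monocyte chemokine Ccl2 (-1.25 ± 0.36). The cytokine Il1b (-2.25 ± 0.58) also passed there, but it was well above background in Cy3 on only 1 of 3 arrays, so its ratio is set against a channel mostly at background. Macrophage markers were at a median of -2.74 in the same samples.

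Genes of the extracellular matrix were higher in the channel labelled SA1-null as a group. Of 43 measured members 37 were above 0, 16 of them on all arrays, with a median of 0.58. The array medians were 1.03, 0.04 and 0.75, so that replicate 2 hardly took part, and without it the median was 0.90. Camera called the list (adjusted p = 3.44e-11, adjusted p = 0.535 with an estimated correlation). No member passed, over all genes (0) or over the list alone (0). Members with the smallest p were Efemp1, the fibrillar collagen gene Col3a1 (1.17 ± 0.60, second probe 0.59), the microfibril gene Mfap2 (0.98 ± 0.47) and the collagen gene Col15a1 (0.77 ± 0.28). With median centring in place of loess, where the median of all genes was -0.30, the matrix median turned to -0.03, which is 0.26 above all genes, and with array weights it was 0.25. Macrophage markers were at -2.74 in the same samples.

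The skeletal patterning and cholesterol synthesis lists were called in that direction as well, and both rested largely on replicate 1. Replicate 1 also differed from the others in slide, Feature Extraction version and signals of Y chromosome genes. Which of these, if any, lay behind the shift of both lists cannot be told from these arrays. Of 34 skeletal genes 28 were above 0, with a median of 0.49 (camera adjusted p = 1.14e-05, adjusted p = 0.946 with an estimated correlation), among them the limb mesenchyme factors Prrx1 (0.86 ± 0.45) and Prrx2 (0.78 ± 0.42), the mesenchymal factor Twist2 (0.62 ± 0.26) and the cartilage factor Sox9 (0.64 ± 0.33, weakest of 3 probes 0.13). Array medians were 1.20, 0.06 and 0.04, and without replicate 1 the median was 0.05 and the call was lost (adjusted p = 0.401). Of 24 cholesterol genes 22 were above 0, with a median of 0.55 (camera adjusted p = 2.26e-06, adjusted p = 0.946 with an estimated correlation). The sterol enzyme genes Nsdhl (1.02 ± 0.70), Cyp51 (0.98 ± 0.83) and Fdft1 (0.85 ± 0.64) were above 0, and Ebp, another of them, was at -0.55 ± 0.37. Array medians were 1.16, 0.09 and 0.22, and without replicate 1 the median was 0.19. With median centring the skeletal median was 0.18 and the cholesterol median 0.09, which is 0.47 and 0.39 above all genes, and with array weights they were 0.19 and 0.27. In both lists 0 members passed, over all genes or over the list alone.

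Of 28 genes of the unfolded protein and amino acid stress response, 21 were above 0, with a median of 0.42 that turned to -0.12 with median centring, 0.18 above all genes there (camera adjusted p = 1.54e-05, adjusted p = 0.535 with an estimated correlation). The serine synthesis gene Psat1 (1.05 ± 0.62), the stress regulators Atf4 (0.78 ± 0.50) and Trib3 (1.69 ± 1.22) and the glutathione-degrading Chac1 (1.45 ± 0.95) had among the smallest p, and 0 passed. The median was 0.22 without replicate 3, 0.21 with every probe on its own and 0.28 with array weights. Of 27 imprinted genes, 20 were above 0, with a median of 0.28 that turned to -0.06 with median centring, 0.24 above all genes there (camera adjusted p = 0.000958, adjusted p = 0.535 with an estimated correlation). The growth factor gene Igf2 (1.35 ± 0.88), Dlk1 (1.05 ± 0.50), the deiodinase gene Dio3 (1.59 ± 0.76) and the growth inhibitor Grb10 (1.03 ± 0.80, weakest of 3 probes 0.17) had among the smallest p, and 0 passed. The median was 0.12 without replicate 1 and 0.16 with array weights.

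The smallest of the called shifts did not keep their direction, and of 18 alternatives besides the other set tests 6 ended the call of the MYC list and 10 that of the ribosomal list. MYC target genes of growth had a median of 0.16, with 25 of 35 above 0, which turned to -0.36 with median centring, -0.06 against all genes there, and to -0.02 with array weights (camera adjusted p = 0.00933, adjusted p = 0.963 with an estimated correlation). Its members with the smallest p, Ptma (-0.49 ± 0.08) and the polyamine enzyme Odc1 (-0.58 ± 0.29), were below 0 at their brightest probes. Each had another probe above 0 (0.13 and 0.15), and a further Odc1 probe was at -0.31 ± 0.12. Ribosomal protein genes had a median of 0.10, with 42 of 65 above 0 (camera adjusted p = 0.0450, adjusted p = 0.963 with an estimated correlation). The median turned to -0.58 with median centring, -0.28 against all genes there. Camera still called the list there, with the median turned (adjusted p = 9.18e-09). With array weights the ribosomal median was -0.05. Rpl5 (-0.58 ± 0.09) and Rpl10a (0.66 ± 0.48) had the smallest p. Without replicate 1 both calls were lost, at medians of 0.09 for the MYC list (adjusted p = 0.506) and 0.02 for the ribosomal list (adjusted p = 0.972). Without replicate 2 the medians were 0.26 and 0.21.

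**Figure D4:**
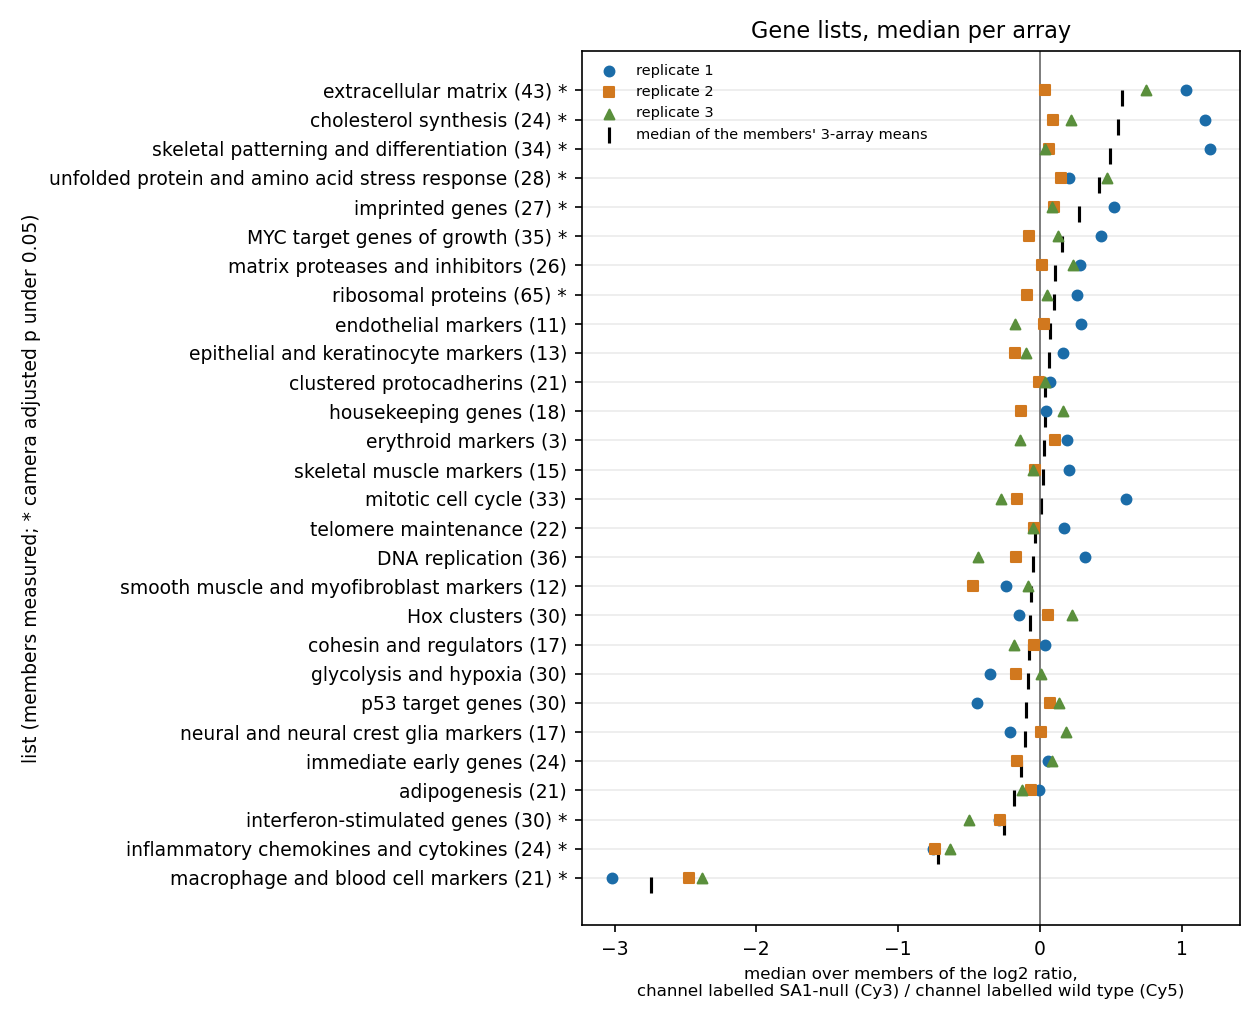
Each point is the median over a list's measured members (y axis) of the log2 ratio of the channel labelled SA1-null over the channel labelled wild type (x axis) on 1 array, and the bar is the median of the members' means. The macrophage list lies at -3.02, -2.47 and -2.39, and the matrix list at 1.03, 0.04 and 0.75, and with median centring, where all genes lie at -0.30, the matrix (0.26), stress response (0.18) and imprinted (0.24) medians stay above all genes, and the MYC (-0.06) and ribosomal (-0.28) medians lie below all genes. Stag1 goes against the labels, and all signs turn over if the channel labels are exchanged.

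The lists closest to cohesin's known roles were not called in the main analysis. Among 17 measured genes of cohesin and its regulators only Stag1 passed, and Stag3 (-0.54 ± 0.42), Pttg1 (-0.43 ± 0.39) and the cohesin subunit Rad21 (-0.25 ± 0.29, second probe 0.41) did not. The median was -0.08, the mean 0.13 and camera's direction upward (adjusted p = 0.884), and with every probe on its own, which counts Stag1 several times, the list was called (median 0.06, adjusted p = 0.0309). Of 21 clustered protocadherin genes, adhesion receptors of neurons, 13 were above 0 with a median of 0.04 (camera adjusted p = 0.758), and Pcdhb3 (-0.44 ± 0.21) and Pcdhb7 (0.33 ± 0.22, above background in Cy5 on 2 of 3 arrays) had the smallest p. Of 30 Hox genes, which set position along the body axis, 14 were above 0 with a median of -0.07 against an upward camera direction (adjusted p = 0.531). The Hox list was called with median centring (adjusted p = 0.00787), at a median of -0.25 that lay 0.05 above all genes. Hoxd8 was at 0.68 ± 0.26 and Hoxb9 at 0.53 ± 0.35. Telomere maintenance genes had a median of -0.04 with camera's direction upward (adjusted p = 0.811), with Dkc1 at 0.47 ± 0.29. In the Hox, protocadherin and telomere lists 0 members passed.

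Growth and damage lists were not called in the main analysis. Mitotic cell cycle genes had a median of 0.01 (camera adjusted p = 0.179), with array medians of 0.61, -0.16 and -0.27, and Hmmr at 0.56 ± 0.55. DNA replication genes had a median of -0.05 (adjusted p = 0.945), with array medians of 0.32, -0.17 and -0.44, and Pcna at -0.55 ± 0.41. Without replicate 1 both lists were called, at medians of -0.21 (camera adjusted p = 0.0131) and -0.26 (0.000145). The mitotic list was also called without replicate 2 (0.20) and without replicate 3 (0.21), with the opposite sign, as was the replication list without replicate 3 (0.12). The mitotic list was called with the slide as a fixed term (0.19), and the replication list with array weights (-0.13) and with median centring (-0.46, which is -0.16 against all genes, adjusted p = 0.00947). The p53 target genes had a median of -0.10 (adjusted p = 0.722), with Pmaip1 at -1.17 ± 0.74. The glycolysis and hypoxia genes were at -0.08 (adjusted p = 0.722), with Aldoa at -0.83 ± 0.21, and without replicate 3 they were called at a median of -0.22. Immediate early genes were at -0.13 (adjusted p = 0.945), with Klf4 at 1.76 ± 0.68 and Egr2 at -0.90 ± 0.41, and housekeeping genes at 0.04 (adjusted p = 0.749). Adipogenesis genes were at -0.19 (adjusted p = 0.934). Matrix proteases and inhibitors had a median of 0.11 and a mean of -0.01 (adjusted p = 0.697), and Mmp3, a matrix protease, passed over all genes at -1.92 ± 0.09 (limma adjusted p = 0.0312).

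Markers of the other cell types were not called in the main analysis. Medians were -0.06 for smooth muscle and myofibroblast markers (camera adjusted p = 0.722, called with array weights at -0.33), 0.02 for skeletal muscle (0.759), 0.03 for the 3 erythroid genes measured (0.913), 0.07 for endothelium (0.945), 0.06 for epithelium and keratinocytes (0.945) and -0.11 for neural and glial cells (0.945). Camera's direction opposed the median for the epithelial and neural lists, and the mean did for the endothelial and epithelial lists (-0.15 and -0.05). Of the sex-linked genes 1 was measured, too few for a test.

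The arrays agreed in part. Across genes, which are not independent replicates, the log2 ratios correlated at Pearson's r of 0.370 between replicates 1 and 2, 0.272 between 1 and 3 and 0.471 between 2 and 3, with Spearman's rho of 0.228, 0.156 and 0.148. The same sign on all arrays was found for 32.4% of genes, where chance gives 25%. All arrays had the same dye orientation, so a dye bias of single genes would raise these agreements too. The SD of the log2 ratios over genes was 0.84, 0.34 and 0.54 on replicates 1, 2 and 3.

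Genes near Stag1 were looked at because DNA around a disrupted gene can keep alleles of the strain it was made in. Of 150 measured genes within 10 Mb of Stag1 in the gene table, 1 was among the 47 called genes with a place there, Pxylp1, where 0.586 was expected. The odds ratio was 1.73 (0.0425 to 10.3, Fisher's exact test, two-sided p = 0.446). That test pools both directions. Besides Stag1, Pxylp1 was the only gene called higher in the channel labelled SA1-null, and it also lay within 5 Mb. Next by p were Plscr2 (-1.32 ± 0.24) and Atp2c1 (-0.84 ± 0.22), which did not pass over all genes.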

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

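The tests of exchanged sample labels, the 2 bright Stag1 probes alone, exchanged scanner channels, macrophages among the fibroblasts, other cell types and dilution were chosen only after the results were seen.

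The spike-in controls, RNAs added at known ratios that no comparison of the report uses, gave a signal on all arrays. Observed log ratios rose with the known ones at slopes of 0.907, 0.937 and 0.923 on replicates 1, 2 and 3 (correlations of 0.998, 0.998 and 0.981). These slopes come from Feature Extraction's own statistics. They show that the files name the dyes rightly and that the software's ratios were slightly compressed. They say nothing on which culture went into which dye, or on the compression of the ratios computed here. Stag1 was at 3.52 in the main analysis and at 4.12 with Agilent's processed signals.

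Stag1 was higher in the channel labelled SA1-null in all 12 values of its 4 probes and 3 arrays, 6 of them from the 2 probes well above background in both channels on all arrays, which an exchange of the channel labels predicts. The deposited values are Cy5 over Cy3 while the sample titles name the knock-out first, which goes with such an exchange. Exchanged scanner channels are argued against by the lowest spike-in slope of 0.907. An intensity-dependent dye bias left after the loess is argued against by the mean of 3.52 of those 2 probes. It lay above the highest of the random probe sets of like intensity (2.19), from which the loess had already removed the trend with intensity. With the dim probes included the percentile was 100 as well. A dye bias tied to sequence, which no dye swap can show here, and transcription from the disrupted gene were not tested. If the channel labels were exchanged, macrophage genes would be higher and matrix genes lower in the SA1-null cultures.

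Macrophage markers were higher in the channel labelled wild type, with 100% of the measured members higher on all arrays, which macrophages among the fibroblasts of 1 genotype's cultures predict. An intensity-dependent dye bias left after the loess is argued against by the median of -2.74. It lay at percentile 0 of random lists of like intensity (central 95% from -0.18 to 0.12), which the loess had already brought near 0. With median centring in place of loess the median was -3.13, which is -2.83 against all genes. Other cell types besides macrophages stay open, since members of the endothelial, epithelial and neural lists went both ways (lowest median -0.11, lower quartiles -0.57, -0.43 and -0.80), and these lists do not decide. Whether macrophages differed in number or in their expression, and whether genotype or differences between embryos and dissections lay behind it, was not tested.

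Matrix genes were higher in the channel labelled SA1-null. Dilution of fibroblast RNA by macrophage RNA as the whole cause is argued against by a comparison with 12 smooth muscle and myofibroblast genes. That holds only if these 12 genes keep a steady level in the fibroblasts, which was not tested. The matrix median lay 0.64 above theirs (bootstrap 95% interval 0.33 to 1.12, which does not measure the spread between culture pairs). Their array medians were -0.24, -0.47 and -0.08, each below the matrix median of the same array. Of the 12 genes, 5 were above 0 and 7 below. Without replicate 2 their median was 0.19, against 0.90 for the matrix list. An intensity-dependent dye bias left after the loess is argued against by the matrix list's percentile of 100 among random lists of like intensity. The loess had already brought such lists near 0, and with median centring in its place the matrix median was -0.03, which is 0.26 above all genes. Replicate 1 alone does not carry the shift, since the median without it was 0.45, but replicate 2 was at 0.04. Genotype, differences between embryos and a dye bias tied to sequence stay open and were not tested.

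Of the 4 sign patterns that the 3 arrays can take, 1, the real one with 58 genes, gave as many genes past the threshold, and the highest of the others gave 0. With 4 patterns the share cannot fall under 0.05, so a chance arrangement of the arrays cannot be told apart by this test.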

How the results depend on the processing

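Array weights were chosen after seeing the data, and the other alternatives were fixed before. Stag1 was higher in the channel labelled SA1-null in every alternative, and the channel labelled wild type was higher for most called genes wherever any were called. The count of 58 genes became 118 (115 higher in the channel labelled wild type) with no background subtraction, 265 (10 higher in the channel labelled SA1-null, 255 in the other) with an offset of 0, 282 (9 and 273) with Agilent's processed signals, 34 (1 and 33) with median centring, 158 (5 and 153) with scale normalization, 92 (89 higher in the channel labelled wild type) with both channels above background, 142 (5 and 137) with an intensity trend and robust variances, 1770 (468 and 1302) with the slide as a fixed term, 185 (18 and 167) with array weights and 132 (5 and 127) at an adjusted p under 0.1. In the fit with the slide as a fixed term, slide 1 held 1 array, so the spread came only from the arrays of slide 2. The count of that fit is therefore not comparable with the count of the main analysis, and no conclusion is drawn from it. With the mean over a gene's probes, 1 gene was higher in the channel labelled SA1-null. No gene passed (0 in all, 0 and 0 per direction) with no filter on dim probes, which raises the number of tests, with a one-sample test without moderation, and with the channels as separate samples. Leaving out 1 replicate gave 0 to 284 genes, 0 to 24 higher in the channel labelled SA1-null and 0 to 260 in the other. Stag1 lost its call with scale normalization (3.68, adjusted p = 0.0712), with no filter on dim probes (3.52, adjusted p = 0.0997), with the channels as separate samples (3.52, adjusted p = 0.0736), with the one-sample test without moderation (3.52, adjusted p = 0.764), and without replicate 2 or replicate 3, with 3.40 to 3.61 over the replicates left out. Lists called went from 10 to 0 with an estimated correlation and to 0 with fry. Agreement between replicates 2 and 3 was 0.593 with Agilent's processed signals. With median centring, where the median of all genes was -0.30, the MYC (-0.36, or -0.06 against all genes) and ribosomal (-0.58, or -0.28) lists turned over. With array weights the MYC (-0.0179) and ribosomal (-0.0517) lists turned over too. Over the replicates left out, the mitotic list lay between -0.21 and 0.21 and the DNA replication list between -0.26 and 0.12. Over the alternatives, lists called in the main analysis kept the call and the sign of the median in 159 results, kept the call with the sign turned in 4 (with median centring, where only the ribosomal list also turned against all genes, and the matrix, stress response and imprinted lists stayed 0.26, 0.18 and 0.24 above them), and lost the call in 34 with the sign kept and in 3 with it turned. Lists not called stayed so in 300 results with the sign kept and 48 with it turned, and gained a call in 9 and 3. Where not named, the cause was not tested. Signal over background, 1.84 to 4.02 as a ratio of medians, limits what can be seen of dim genes. The number of arrays limits the precision. The slide as a random block was not run, since 3 arrays gave no estimate.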

Other observations

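The values in this part were singled out after they were seen, and no test was planned for them.

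Several genes of the Y chromosome set replicate 1 apart from the others, and others did not. Processed signals of Ddx3y, Eif2s3y and Kdm5d were 618 to 5870 on replicate 1 and 2.60 to 7.08 on replicates 2 and 3. A general difference in sensitivity between slides or software versions is argued against as their cause. Shares of probes above background were alike, at 60.7%, 60.6% and 65.9% in Cy3 and 67.0%, 63.0% and 61.9% in Cy5. Replicate 1 was also the only array on its slide and with its Feature Extraction version. Which of these traits lay behind its other differences cannot be told. Ddx3y, Eif2s3y and Kdm5d, and both probes of Uty, were well above background in both channels of replicate 1 and in neither channel of replicates 2 and 3. Sry, Rbmy, Usp9y and Zfy1 were not above background on replicate 1, and 1 of 2 Zfy2 probes was above background in both channels of all 3 arrays. Xist, expressed from the inactive X chromosome, was above background in Cy5 on replicates 2 and 3 and in Cy3 on replicate 3, and in neither channel of replicate 1. The log2 ratio of the channel labelled SA1-null over the channel labelled wild type on replicate 1, whose sign turns over if the channel labels are exchanged, was -0.24 for Ddx3y, -0.55 for Eif2s3y and -0.30 for Kdm5d.

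Single markers of other cell types moved both ways, and their lists were not called. Cd34, a marker of endothelium and of blood and stromal progenitors, was lower in the channel labelled SA1-null, at -1.65 ± 0.73 (SD, n = 3), and passed when adjusted over the endothelial list alone, as did the troponin gene Tnni2, lower on 3 of 3 arrays, over the skeletal muscle list. The keratin gene Krt8 (-1.02 ± 0.42) and the myelin gene Mbp (-1.53 ± 1.07) did not pass. Higher in the channel labelled SA1-null on 3 of 3 arrays, without passing, were S100b (1.35 ± 1.70), Tubb3 (0.50 ± 0.14) and Foxd3 (0.32 ± 0.07) of the neural list, Emcn (0.81 ± 0.66) and Eng (0.62 ± 0.61) of the endothelial list, Krt7 (0.50 ± 0.41) and Cdh15 (0.53 ± 0.47). Near Stag1, Plscr2 (-1.32 ± 0.24) passed only when adjusted over the neighbours alone (adjusted p = 0.0485 in limma).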
